A study of Rattus norvegicus with 127 samples.

How the data were processed

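Total RNA from the pubocaudalis muscle of Sprague Dawley rats was isolated with a kit for fibrous tissue after storage in RNAlater, and 50 to 100 ng of it was hybridised with a custom nCounter codeset, per the labels' protocols. The deposited value table holds 1 column for each of 127 samples and 134 probes. Its values are a normalized signal on a linear scale, as the authors deposited them; the software, the control probes and the genes used for scaling are not given in the sources used here. In each sample the values are whole multiples of a step, so the count behind each value could be recovered. All 16829 values above the floor (100.0%) were whole within 0.05 of a count, and 189 values stood at the floor of 0.1 that replaces a count of 0. The value of 1 count ran from 0.563 to 4.281 between samples, which is the factor the authors applied. Recovered total counts ran from 366294 to 1824478 per sample (median 1344374), and totals of the deposited values from 543939 to 2791351. The depth of a sample sets a counting error that is small for most genes and large for probes near 0. The values are relative to a scale that no source describes, so the analysis was repeated with each sample centred on its panel median.

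The value table has no gene names. The authors' deposited workbook gives, in 5 sheets, log2 fold changes of their own comparisons with a p-value and a q-value for some genes, with no test named. Its 136 gene names were matched to the table by value. For each probe the log2 ratios of group means were set against the authors' fold changes of 8 comparisons, and names were assigned one to one at the smallest difference. All 134 probes received a name, and Ppard and Pparg were left without one. The median difference was 0.0049 (log2), 132 probes had at least 4 values to compare, and 130 were the best match both ways. App, Ccn2, Dcn and Nfkbia were not, and Ccn2 and Dcn rest on 2 values and 1 value. Prkaa1 and Ikbkb were the best match by a narrow margin only. Each had 2 of 4 values within 0.05, with median differences of 0.43 and 0.23. As a check not used for the match, 133 of 133 neighbouring probes came out in alphabetical order. The authors' deposited columns for SBI days 3 and 7 were also left out of the match. Over all samples they differed from the value table by a median of 0.163 and 0.1001, and of 502 and 247 subsets of samples the closest was replicates 1 to 6 at both days (0.0054 and 0.0052). At day 7 replicates 1, 2, 3, 4, 5 and 8 came about as close (0.0061), since replicates 6 and 8 have the same counts. With the closest subsets, chosen on these same columns, both values lay within 0.05 in 128 of 132 probes, Prkaa1 and Ikbkb among them. The workbook's blocks headed SKM against injury hold the fold changes of SKM against saline. The authors' fold changes and q-values were used for names and checks only.

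Samples were grouped by the labels into the 18 groups. Of the SBI day 3 samples, replicates 6 and 7, and of the SBI day 7 samples, replicates 5 and 7 and replicates 6 and 8, had identical counts in all 134 genes and differed only in the factor; no other pair shared over 12 counts. Each such pair was averaged and counted once, which left 124 samples. Values were taken as log2(value + 1), and fold changes are on that scale, which understates the change of low genes. All groups were fitted together, with 1 mean per group, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg over the 134 genes within each comparison, at a threshold of 0.05. Counts were recovered and names matched in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The comparisons were each injury day against uninjured muscle, SKM against saline at each time, saline against injury alone, the differences between SKM effects, day against day, and a moderated F test over the 7 injury days.

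Of 22 gene lists fixed before the data were examined, 13 had genes on the panel. The 11 with at least 5 genes were tested with fry, which asks whether the genes of a set move on balance one way, and with camera at an estimated correlation. They are acute inflammation, type 2 and regulatory immune, myogenesis, adult muscle fibre, muscle anabolism, muscle catabolism, ECM structure, ECM remodelling enzymes, fibroblast and TGF-beta, vasculature and neuromuscular junction. Camera sets a list against the rest of the panel, which is a question other than that of fry. A list called by fry and not by camera has therefore not failed the same test. Macrophage markers (3 genes) and lymphocyte markers (4 genes) were too small, and 9 lists, among them the housekeeping genes, had no gene on the panel. The submitters designed the panel for pathways of muscle injury, so a list's direction is set by which of its genes were put on the panel. The injury score was compared between SKM and saline by an exact permutation test, two-sided, over all arrangements of the samples; the delayed groups at days 3 and 7 have no score, since 0 genes were called at their matched injury days.

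The text names genes by a rule fixed in advance: in each comparison of injury with uninjured muscle and of SKM with saline, up to 10 higher and 10 lower called genes by size of change, with up to 2 genes of each list by smallest p, and the 5 smallest p-values where fewer than 5 genes pass. For the other comparisons it takes up to 5 genes in each direction, or the 3 smallest p-values where none passes.

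On simulated data with 40 of 134 genes changed in 20 simulations, the fit of delayed SKM at day 7 recovered 37.9, 67.3 and 93.5% of genes changed by a log2 value of 0.5, 1 and 2, with 3.1% false calls. For SBI day 1 the shares were 13.6, 40.8 and 69.6%, with 3.6% false calls, and for SBI day 3 they were 23.2, 50 and 81.5%, with 3.8%. The simulation drew the genes independently, with 1 spread per gene for all groups and no shift of a whole sample. Real samples shared such shifts. Other splits of them called up to 36 genes for delayed SKM at day 7 (median 0) and 95 at SBI day 3 (median 1). A split that moves few samples keeps much of the real difference, so these highest counts do not measure the shifts alone. The simulated shares therefore need not hold for the real data. The alternatives fixed in advance were a pseudocount of 10, leaving out the lowest 25% of genes, centring on the panel median, a fit of the compared groups only, array weights, camera for fry, the replicate number as a block, and leaving out each sample in turn. Those added after seeing the data were voom weights on the recovered counts, only samples of at least 1000000 counts, the repeated samples kept separate, SBI days 3 and 7 from replicates 1 to 6, and the F test without SBI day 84. Centring on housekeeping genes could not be run, since the panel values hold none of them.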

Results

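RNA of the pubocaudalis, a muscle of the rat pelvic floor, was measured in Sprague Dawley rats that were uninjured or had received a simulated birth injury (SBI). Some injured rats then received an injection of saline or of SKM, a hydrogel made from the extracellular matrix (ECM) of skeletal muscle, either immediately or after a delay. A custom nCounter panel, which counts RNA molecules captured by barcoded probes, covered 134 genes of inflammation, muscle formation and breakdown, the matrix, blood vessels and the neuromuscular junction. The 127 deposited samples fell into 18 groups. In 3 pairs of samples (1 pair of SBI day 3 and 2 pairs of SBI day 7) the recovered counts of all 134 genes were identical, so the members differed by less than the sampling noise and were counted as 1 sample, which left 124. No label says whether the samples of a group came from separate animals, so the p-values measure the spread between these samples.

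The time course of injury alone held 3 uninjured samples and 3 samples at day 1, 8 at day 3, 6 at day 7, 3 at day 10, 6 at day 31, 6 at day 35 and 6 at day 84. Immediate injection gave 9 saline and 9 SKM samples at day 3, and 9 saline and 8 SKM samples at day 7. Delayed injection gave 9 saline and 9 SKM samples at day 3, 10 saline and 9 SKM samples at day 7, and 5 saline and 6 SKM samples at week 8. The recovered total count per sample ran from 366294 to 1824478, with a median of 1344374. The samples of SBI day 84 and of week 8 had totals between 629324 and 872262 and a mean of 5.2 to 5.5 probes at 0 counts, against at most 3.17 in any other group. Their panel medians also stood lowest. The mean of the samples' median log2 value was 8.46 ± 0.18 at SBI day 84 (SD, n = 6), 8.51 ± 0.14 for saline at week 8 (n = 5) and 8.45 ± 0.17 for SKM at week 8 (n = 6), against 10.23 ± 0.31 in uninjured muscle (n = 3) and group means of 9.51 to 10.95 elsewhere. Because the panel was chosen for genes that respond to injury, its median is no neutral reference, and changes are given on the deposited scale with the values after centring each sample on its median wherever the 2 scales part.

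**Figure D1:**
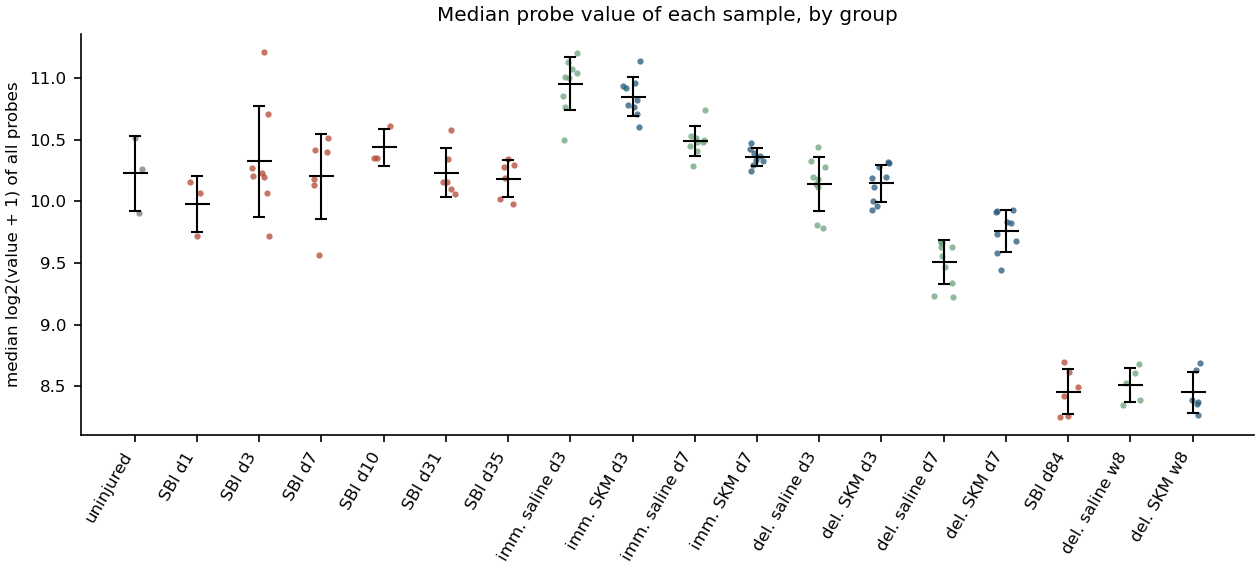
Median log2(value + 1) of the 134 panel genes in each sample (vertical axis) by group (horizontal axis), with the group mean and SD. The samples of SBI day 84 and of week 8 lie between 8.25 and 8.70, below every other sample.

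The first question was how the injured muscle differed from uninjured muscle over time. On day 1, inflammatory genes stood far above uninjured muscle, while genes of blood vessels, muscle growth and the contractile apparatus stood below it (n = 3 and 3). Ccl2, which attracts monocytes, rose by 6.57 ± 0.95 (log2 fold change ± SE, as for all values given this way), the inflammatory cytokine gene Il1b by 6.32 ± 1.65, and Cxcr2, a chemokine receptor of neutrophils, by 6.25 ± 1.72. Timp1, an inhibitor of matrix metalloproteinases, rose by 4.29 ± 0.65 and the matrix glycoprotein gene Thbs1 by 4.10 ± 0.77. Among the genes that fell were Timp4 (-3.83 ± 0.53), Mstn, which encodes the muscle growth inhibitor myostatin (-3.78 ± 0.84), Col1a1 (-3.41 ± 0.63), the myogenic transcription factor gene Myod1 (-2.26 ± 0.45) and Grb10, an adaptor that dampens insulin signalling (-2.83 ± 0.28). Limma called 87 of the 134 genes at an adjusted p under 0.05, 29 of them higher and 58 lower.

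By gene list at day 1, 9 of 14 acute inflammation genes were higher and none was lower (9 higher adjusted over the list alone). Of the 9 vascular genes 7 were lower (7 adjusted over the list alone), with Vegfa at -2.05 ± 0.36 and Angpt1, a ligand that stabilises vessels, at -1.98 ± 0.32. Of the 12 muscle anabolism genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone), led by Rps6kb1 at -1.58 ± 0.23 and Smad4 at -0.93 ± 0.16. Of the 8 muscle catabolism genes 5 were lower, among them Foxo1 (-1.41 ± 0.28), and the protease gene Ctsl was higher (2.32 ± 0.40), with the same counts adjusted over the list alone. In the myogenesis list 6 of 10 genes were lower and 1 higher (7 and 1 adjusted over the list alone), and in the adult muscle fibre list 4 of 8 were lower (4 adjusted over the list alone), including Dmd (-2.28 ± 0.42) and Myh1, a fast myosin heavy chain gene (-2.60 ± 0.71). Macrophage and lymphocyte lists were too small to test as sets. The macrophage genes Ccr2 (2.88 ± 0.58) and Arg1 (3.02 ± 1.05) rose while the fibre genes fell, and Adgre1, a surface marker of macrophages, was at 0.45 ± 0.94 (adjusted p = 0.668). The lymphocyte genes Foxp3 (-3.08 ± 0.65) and Gata3 (-2.18 ± 0.83) fell. The rotation test fry called acute inflammation as higher (adjusted p = 0.00165) and 8 lists as lower, those above with ECM structure, fibroblast and TGF-beta, and neuromuscular junction. Camera, which sets each list against the rest of the panel, called no list (adjusted p from 0.926 to 0.987). The type 2 and regulatory immune list and the ECM remodelling enzymes were not called by fry (adjusted p = 0.159 and 0.112). The second of these had a positive median of 0.66 although fry gave its direction as down. The panel median lay lower by a log2 value of -0.25, and after centring limma called 89 genes, 36 higher and 53 lower. Fry then called 2 lists as higher and 7 as lower, with the type 2 and regulatory immune list gained and the fibroblast and TGF-beta list lost. In a fit of these groups only it called 5 lists, all lower, without acute inflammation.

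On day 3, matrix and inflammatory genes and the embryonic myosin gene were higher, and the genes of the adult contractile apparatus were lower (n = 8 against 3). The macrophage elastase gene Mmp12 rose by 5.40 ± 1.87, Il1b by 5.10 ± 1.36, Timp1 by 4.51 ± 0.54, the matrix gene Tnc by 4.06 ± 0.68, the metalloprotease gene Adam12 by 3.83 ± 0.51 and Myh3, the embryonic myosin heavy chain gene of forming fibres, by 3.52 ± 0.88. Mylk2, a kinase of skeletal muscle myosin (-3.70 ± 0.72), Mstn (-3.44 ± 0.70), the fast troponin gene Tnnt3 (-3.36 ± 0.52), Myh1 (-3.31 ± 0.59) and the skeletal actin gene Acta1 (-2.74 ± 0.56) fell. Limma called 99 genes, 52 higher and 47 lower, and 91 with voom weights on the recovered counts.

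Of the adult muscle fibre list, 7 of 8 genes were lower at day 3 (8 adjusted over the list alone; fry adjusted p = 1.76e-05). Beside them all 3 macrophage genes were higher, with Adgre1 at 2.70 ± 0.78 and Ccr2 at 2.03 ± 0.48. ECM structure had 4 of 5 genes higher (4 adjusted over the list alone; fry adjusted p = 1.34e-05), and of the 13 ECM remodelling enzymes 7 were higher and 2 lower (7 and 2 adjusted over the list alone; fry adjusted p = 0.00061). Acute inflammation had 9 of 14 genes higher (9 adjusted over the list alone; fry adjusted p = 0.000905), and the type 2 and regulatory immune list 5 of 8, among them Tgfb1 at 2.19 ± 0.39, with Foxp3 lower at -3.43 ± 0.54 (5 and 1 adjusted over the list alone; fry adjusted p = 0.0152). The vascular list had 5 of 9 genes lower and 1 higher (5 and 1 adjusted over the list alone; fry adjusted p = 1.18e-05), with Vegfa at -2.28 ± 0.30 and Vegfb at -1.89 ± 0.27. Muscle anabolism had 7 of 12 genes lower and 2 higher, and muscle catabolism 4 of 8 lower and 1 higher, with the same counts adjusted over each list alone (fry adjusted p = 9.54e-06 and 0.00293). In the neuromuscular junction list 3 of 5 genes were higher and 1 lower (3 and 1 adjusted over the list alone; fry adjusted p = 0.0346), including Musk, the receptor kinase that organises the synapse (1.65 ± 0.53). Myogenesis had members on both sides, 5 higher and 4 lower of 10 (5 and 4 adjusted over the list alone; fry adjusted p = 0.628), with Hgf at 1.86 ± 0.33 and Fgf2 at -3.19 ± 0.50. The fibroblast and TGF-beta list had 3 higher and 2 lower of 8 (3 and 2 adjusted over the list alone; fry adjusted p = 0.104). Among the lymphocyte genes Foxp3 alone passed. Against the rest of the panel camera called none of the 9 lists that fry called (adjusted p from 0.604 to 0.683). After centring fry called 9 lists, with the fibroblast and TGF-beta list gained as higher and the neuromuscular junction list lost.

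**Figure D2:**
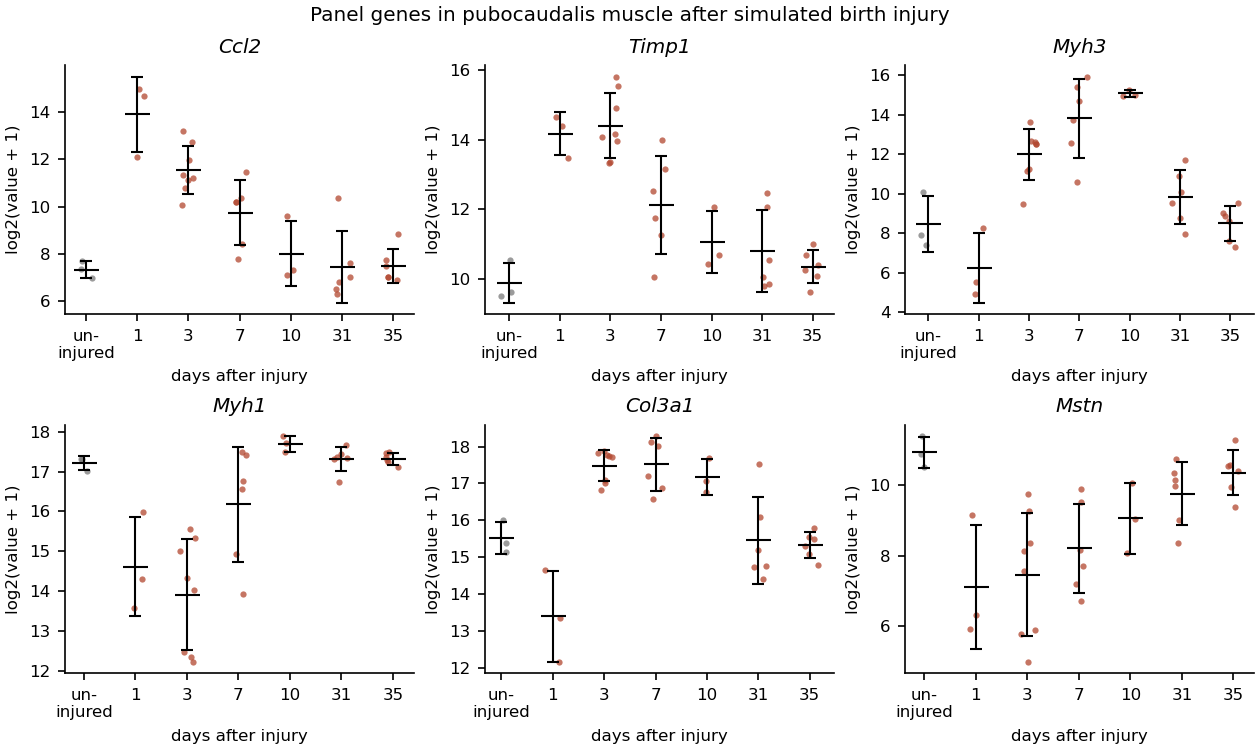
Log2(value + 1) of Ccl2, Timp1, Myh3, Myh1, Col3a1 and Mstn in each sample (vertical axes) of uninjured muscle and of SBI days 1, 3, 7, 10, 31 and 35 (horizontal axes), with the mean and SD of each group. Ccl2 and Timp1 are highest at days 1 and 3, Myh3 at day 10, and Myh1 and Mstn are lowest at days 1 and 3.

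On day 7, Myh3 stood 5.34 ± 0.92 above uninjured muscle (n = 6 against 3), and Sln, a regulator of the muscle calcium pump, 3.21 ± 0.61 above it. Il1b (4.89 ± 1.42), Adam12 (2.55 ± 0.54), Ccl2 (2.40 ± 0.82), Timp1 (2.23 ± 0.57) and the collagen gene Col3a1 (2.00 ± 0.43) were also higher. Mstn (-2.71 ± 0.73), Acta1 (-1.96 ± 0.58), Vegfa (-1.80 ± 0.32), Myod1 (-1.79 ± 0.39) and the signal transducer gene Smad3 (-1.68 ± 0.34) were lower. Limma called 77 genes, 41 higher and 36 lower, and 68 with voom weights. The ECM remodelling enzymes had 8 of 13 genes higher and 1 lower (8 and 1 adjusted over the list alone; fry adjusted p = 0.000885), with Mmp14, a membrane-bound metalloprotease, at 1.75 ± 0.40, and ECM structure 4 of 5 higher (4 adjusted over the list alone; fry adjusted p = 0.00132). Acute inflammation had 4 of 14 genes higher (3 adjusted over the list alone), the type 2 and regulatory immune list 3 of 8 higher and 1 lower (2 and 1), and the neuromuscular junction list 2 of 5 higher (0 adjusted over the list alone), all called as higher by fry (adjusted p = 0.0375, 0.0474 and 0.0474). Muscle anabolism had 9 of 12 genes lower (9 lower and 1 higher adjusted over the list alone), muscle catabolism 4 of 8 lower and 1 higher (4 and 1) and vasculature 4 of 9 lower and 1 higher (4 and 1), all called as lower (adjusted p = 0.000112, 0.000885 and 0.0196). The adult muscle fibre list had 2 of 8 genes lower (2 adjusted over the list alone; fry adjusted p = 0.111), with Adgre1 at 2.47 ± 0.81. Camera called none of the lists against the rest of the panel (adjusted p from 0.558 to 0.58). A fit of the 2 compared groups only, which estimates the spread from these 9 samples, called 2 genes and 0 lists. The main fit uses 1 spread per gene over all groups, so its p-values are too small for genes that vary more among the SBI day 7 samples. Myh3 and Ttn, for example, had an SD of 1.99 and 2.27 at SBI day 7, against 1.13 and 1.18 for immediate saline at day 7. Other genes varied less there, such as Il2 (0.77 against 1.96). Without uninjured replicate 2 limma called 44 genes.

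On day 10, Myh3 (6.60 ± 1.06) and Sln (4.13 ± 0.70) were far above uninjured muscle (n = 3 and 3). Musk (1.97 ± 0.64), Col3a1 (1.66 ± 0.49), the receptor gene Erbb2 (1.64 ± 0.52), Tgfb1 (1.38 ± 0.47), the myogenic factor gene Myf5 (1.29 ± 0.37), Mmp2 (1.16 ± 0.39), the growth factor receptor gene Igf1r (0.75 ± 0.22) and App (0.63 ± 0.22) were higher, and Smad3 (-1.20 ± 0.39) and Vegfa (-1.20 ± 0.36) lower. These were the 12 genes that limma called. Fry called 4 lists as higher, each at an adjusted p of 0.0328, namely myogenesis (2 of 10 genes), ECM structure (1 of 5), ECM remodelling enzymes (1 of 13) and neuromuscular junction (2 of 5), with the same counts adjusted over each list alone. With camera the adjusted p lay between 0.616 and 0.624. The panel median lay higher by 0.21, and after centring 5 genes were called, 3 higher and 2 lower, and 0 lists by fry. The count was 4 without uninjured replicate 1, 2 without uninjured replicate 2 and 2 without SBI day 10 replicate 3, and 4 in a fit of these groups only.

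At days 31 and 35 limma called 0 genes against uninjured muscle (n = 6 against 3 at each day), with 20 and 7 genes at an unadjusted p under 0.05. With voom weights the counts were 2 and 0, and with array weights 7 and 0. The smallest p-values at day 31 belonged to Myod1 (-1.32 ± 0.39), Vegfa (-1.02 ± 0.32), Igf1r (0.59 ± 0.19), the cytokine gene Il33 (0.73 ± 0.24) and the kinase gene Akt1 (-0.37 ± 0.13), each with an adjusted p of 0.105. At day 35 the smallest belonged to Kdr, a receptor of VEGF (-0.85 ± 0.27), Myod1 (-1.07 ± 0.39), Pdgfra (0.60 ± 0.24), Il33 (0.56 ± 0.24) and Col1a1 (-1.19 ± 0.55), with adjusted p-values from 0.312 to 0.69. Myh3 was at 1.36 ± 0.92 on day 31 and 0.02 ± 0.92 on day 35, and Adgre1 at 1.04 ± 0.81 and 0.87 ± 0.81. Fry and camera called 0 of the 11 lists at either day, and the adult muscle fibre list at day 31 (median -0.01, mean 0.22) and the type 2 and regulatory immune list at day 35 (median 0.05, mean -0.17) had medians and means of opposite sign. Without uninjured replicate 3, 6 genes were called at day 31.

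At day 84 every called gene was lower than in uninjured muscle, 108 of 134 genes (n = 6 against 3), but the panel median of these samples also lay lower by a log2 value of -1.77. Among them were Col1a1 (-3.96 ± 0.55), Mmp9 (-3.15 ± 0.48) and Mstn (-3.15 ± 0.73). After centring 2 genes were called, Col1a1 lower (-2.19 ± 0.49) and Igf1r higher (0.68 ± 0.16), which on the deposited scale was lower (-1.09 ± 0.19). The other 106 calls were lost on the centred scale. Fry called all 11 lists as lower on the deposited scale and 0 after centring, and camera called none against the rest of the panel (adjusted p from 0.0883 to 0.903). The authors' deposited table of the time course has no column for day 84.

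Between injury days, single genes were compared and no list was tested. From day 3 to day 7 (n = 8 and 6), Myh1 rose by 2.27 ± 0.47, Foxp3 by 2.09 ± 0.43, the slow myosin gene Myh7 by 1.84 ± 0.58, Myh3 by 1.82 ± 0.70 and Mylk2 by 1.82 ± 0.57. Il6 (-2.33 ± 0.64), Timp1 (-2.28 ± 0.43), Tnc (-1.90 ± 0.54), Thbs1 (-1.85 ± 0.51) and Ccl2 (-1.80 ± 0.63) fell. Limma called 47 genes, 26 higher and 21 lower, and after centring, with a shift of -0.12, 61 genes, 42 higher and 19 lower. The count was 31 without SBI day 7 replicate 5 and 4 in a fit of these groups only. From day 7 to day 31 (n = 6 and 6), Myh3 (-3.98 ± 0.75), Adam12 (-3.54 ± 0.44), Il1b (-3.44 ± 1.16), Il6 (-2.96 ± 0.68) and Col1a1 (-2.46 ± 0.45) fell, and Ttn, the gene of the giant sarcomere protein titin (1.88 ± 0.64), Mstn (1.55 ± 0.59), Mylk2 (1.46 ± 0.61), the ubiquitin ligase gene Fbxo32 (1.42 ± 0.40) and Mybpc2 (1.31 ± 0.51) rose. Limma called 56 genes there, 30 higher and 26 lower, and 48 after centring. The count was 24 without SBI day 7 replicate 1, 34 without its replicate 2, 35 without its replicate 6, 37 without SBI day 31 replicate 2, 37 without its replicate 5 and 7 in a fit of these groups only. Over the 7 injury days together, 132 of 134 genes differed by the moderated F test, and 123 after centring.

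The second question was whether SKM changed the response when it was injected immediately. At day 3 after immediate injection limma called 0 genes between SKM and saline (n = 9 and 9), with 8 genes at an unadjusted p under 0.05, 0 with voom weights and 31 with array weights. The smallest p-values were those of Vegfa (-0.55 ± 0.21), the neutrophil collagenase gene Mmp8 (-1.62 ± 0.64), Myh3 (1.51 ± 0.61), Nfkbia (-0.72 ± 0.30) and the chemokine gene Ccl3 (-1.53 ± 0.65), all with an adjusted p of 0.54. Fry called 0 lists. The myogenesis list had a mean of 0.36 (fry adjusted p = 0.267) and was the 1 list called by camera (adjusted p = 0.0315). After centring, with a shift of -0.10, fry called it as well (adjusted p = 0.041). The acute inflammation list had a mean of -0.72 (fry adjusted p = 0.787), with Nos2 at -2.07 ± 1.02.

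At day 7 after immediate injection limma again called 0 genes (n = 8 and 9), with 7 at an unadjusted p under 0.05, 0 with voom weights and 4 with array weights. The smallest p-values were those of the collagen-binding integrin gene Itga1 (-0.44 ± 0.14, adjusted p = 0.344), Ccn2 (-0.86 ± 0.32), Itgb1 (-0.27 ± 0.10), Myh3 (-1.52 ± 0.63) and Myf5 (-0.51 ± 0.22). Fry and camera called 0 lists. The means of the 11 tested lists ran from -0.48 for ECM structure to 0.10 for the type 2 and regulatory immune list, and the panel median differed by -0.13. The muscle anabolism list had a median and a mean of opposite sign at both days (-0.01 and 0.01 at day 3). The name Ccn2 rests on 2 matched values and that of Nfkbia on a match that was not the best both ways.

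The injury score gave each sample its mean log2 distance from uninjured muscle over the genes called at the matched injury day, signed by the direction of injury, so that 0 is the uninjured mean. At day 3 it was 2.08 ± 0.41 with SKM and 2.26 ± 0.59 with saline (SD, n = 9 each, 99 genes), a difference of -0.182 (exact permutation test, two-sided, p = 0.455, 48620 arrangements). At day 7 it was 1.33 ± 0.60 with SKM (n = 8) and 1.48 ± 0.61 with saline (n = 9, 77 genes), a difference of -0.147 (exact permutation p = 0.62, 24310 arrangements). Leaving out 1 sample moved the difference at day 3 to between -0.315 (without saline replicate 2) and -0.095 (without saline replicate 8), and at day 7 to between -0.306 (without SKM replicate 7) and -0.0023 (without saline replicate 7). Injury alone, on whose samples the genes were chosen, had 2.08 ± 0.52 at day 3 (n = 8) and 1.46 ± 0.71 at day 7 (n = 6). At week 8 the difference was 0.0823 over 108 genes (exact permutation p = 0.4, 462 arrangements, n = 6 and 5), on a score that carries the scale of the day 84 samples, and between 0.0384 (without saline replicate 4) and 0.133 (without SKM replicate 5) with 1 sample left out. All 3 scores had an adjusted p of 0.62, and SKM samples lay above the saline mean in 3 of 9, 3 of 8 and 4 of 6. Depth was uneven at immediate day 3. Saline replicates 4, 5, 7, 8 and 9 and SKM replicates 7, 8 and 9 had totals of 530033 to 748527. The other samples had 1642385 to 1824478. These shallower samples scored 2.33 to 2.96 with saline, against 1.20 to 2.56 in the deeper ones, and 1.75 to 2.74 with SKM, against 1.57 to 2.34. The score comparison does not account for depth.

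**Figure D3:**
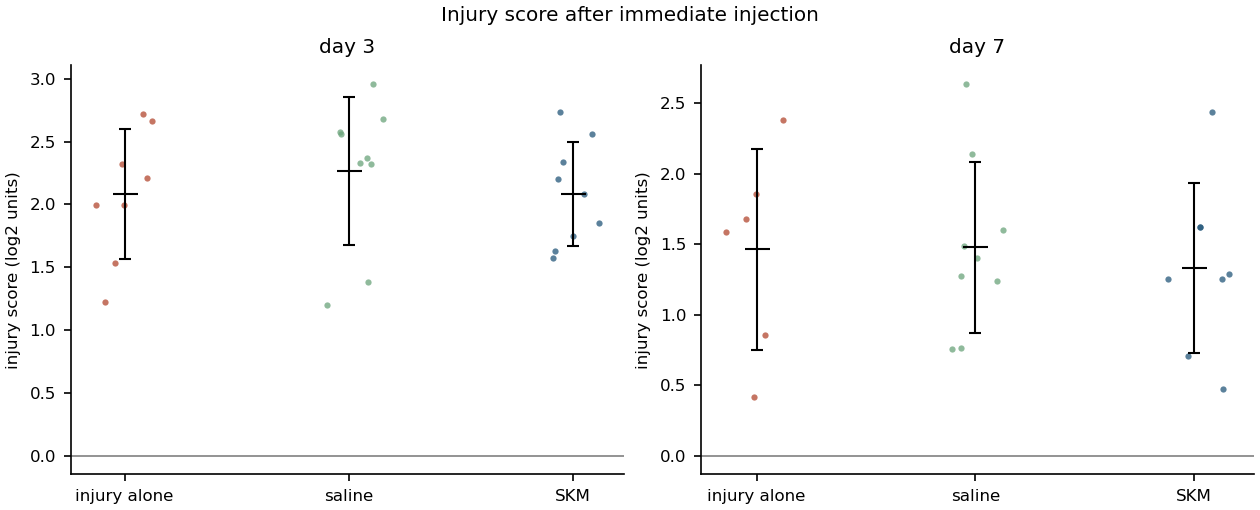
Injury score of each sample (vertical axis, mean signed log2 distance from uninjured muscle) at days 3 and 7 (panels) for injury alone, immediate saline and immediate SKM, with the mean and SD. The SKM and saline samples overlap at both days.

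The third question was what SKM did when it was injected after a delay. At day 3 after delayed injection 9 genes were higher with SKM than with saline (n = 9 and 9), and no gene was called lower. Il1b rose by 2.88 ± 0.95, Nkg7, a gene of cytotoxic lymphocyte granules, by 2.34 ± 0.56 and Adgre1 by 2.10 ± 0.54. The transcription factor gene Irf5 rose by 1.11 ± 0.30, the kinase gene Rps6ka1 by 1.06 ± 0.29, Tgfb1 by 0.89 ± 0.27, Myd88, the adaptor of Toll-like receptors, by 0.85 ± 0.24 and Stat6 by 0.71 ± 0.22. These are among the 9 genes that limma called, with adjusted p-values from 0.00719 for Nkg7 to 0.0447 for Il1b; voom weights also gave 9. Stat6 lay above the saline mean in 8 of 9 SKM samples and each of the others named here in 9 of 9.

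By gene list at this time, 2 of 14 acute inflammation genes were higher (2 adjusted over the list alone; mean 1.28, fry adjusted p = 0.0791) and 2 of 8 in the type 2 and regulatory immune list (3 adjusted over the list alone; mean 0.55, fry adjusted p = 0.0791). Of the 3 macrophage genes, Adgre1 passed, and 2 adjusted over the list alone; Ccr2 was at 0.87 ± 0.33 (adjusted p = 0.0915). The adult muscle fibre list had a mean of -0.58 with no gene called (fry adjusted p = 0.204), with Acta1 at -0.67 ± 0.39, and Mmp12 was at 3.76 ± 1.30 (adjusted p = 0.0578). Fry and camera called 0 of the 11 lists. After centring, with a shift of 0.01, limma called 15 genes, all higher, and fry called the 2 immune lists (adjusted p = 0.0414 and 0.00715). A fit of these groups only called 48 genes, 23 higher and 25 lower. The count was 15 without SKM replicate 3 and 4 without SKM replicate 8.

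At day 7 after delayed injection 20 genes were higher with SKM and none was lower (n = 9 and 10). Mmp12 rose by 3.69 ± 1.27, Il1b by 2.53 ± 0.93, Adgre1 by 2.10 ± 0.53, the cytokine gene Tnf by 2.00 ± 0.67, Nkg7 by 1.76 ± 0.54, Ccl2 by 1.63 ± 0.53 and the receptor gene Il10ra by 1.47 ± 0.51. Irf4 and Ccr2 (1.16 ± 0.36 and 1.16 ± 0.32), Tgfb1 (1.03 ± 0.26), Mmp14 (0.99 ± 0.26), Hgf, a growth factor that activates muscle stem cells (0.78 ± 0.23), Timp2 (0.48 ± 0.14) and the endothelial receptor gene Tie1 (0.45 ± 0.14) were also higher. Adjusted p-values ran from 0.00877 to 0.049, and each of the 20 genes lay above the saline mean in 8 or 9 of the 9 SKM samples.

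Fry called 4 lists as higher at this time. ECM remodelling enzymes had 5 of 13 genes higher (7 adjusted over the list alone; fry adjusted p = 0.0122), the type 2 and regulatory immune list 3 of 8 (5 adjusted over the list alone; 0.0122), ECM structure 0 of 5 (2 adjusted over the list alone; 0.0189) with Col1a1 at 0.87 ± 0.35 and Col3a1 at 0.71 ± 0.28, and acute inflammation 4 of 14 (6 adjusted over the list alone; 0.0452). Camera called none of them against the rest of the panel (adjusted p from 0.564 to 0.58). Of the macrophage genes 2 of 3 were higher (3 adjusted over the list alone). Muscle anabolism had no gene called (mean -0.01, fry adjusted p = 0.534), with the kinase gene Rps6kb1 at -0.35 ± 0.13. The panel median was higher with SKM by 0.25. After centring limma called 10 genes, 6 higher (among them Adgre1, Tgfb1, Irf5, Mmp14 and Ccr2) and 4 lower, all 4 of the muscle anabolism list (Rps6kb1, Eif4ebp1, Rheb and Mtor, chosen for mention after their values were seen), which fry then called as lower (adjusted p = 0.0406) as the 1 list. Limma with voom weights called 13 genes and a fit of these groups only 12. The count was 0 without SKM replicate 8, 9 without SKM replicate 9, 43 without SKM replicate 1 and 31 without SKM replicate 6, and 7, 13, 12 and 33 without saline replicates 3, 4, 8 and 10.

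**Figure D4:**
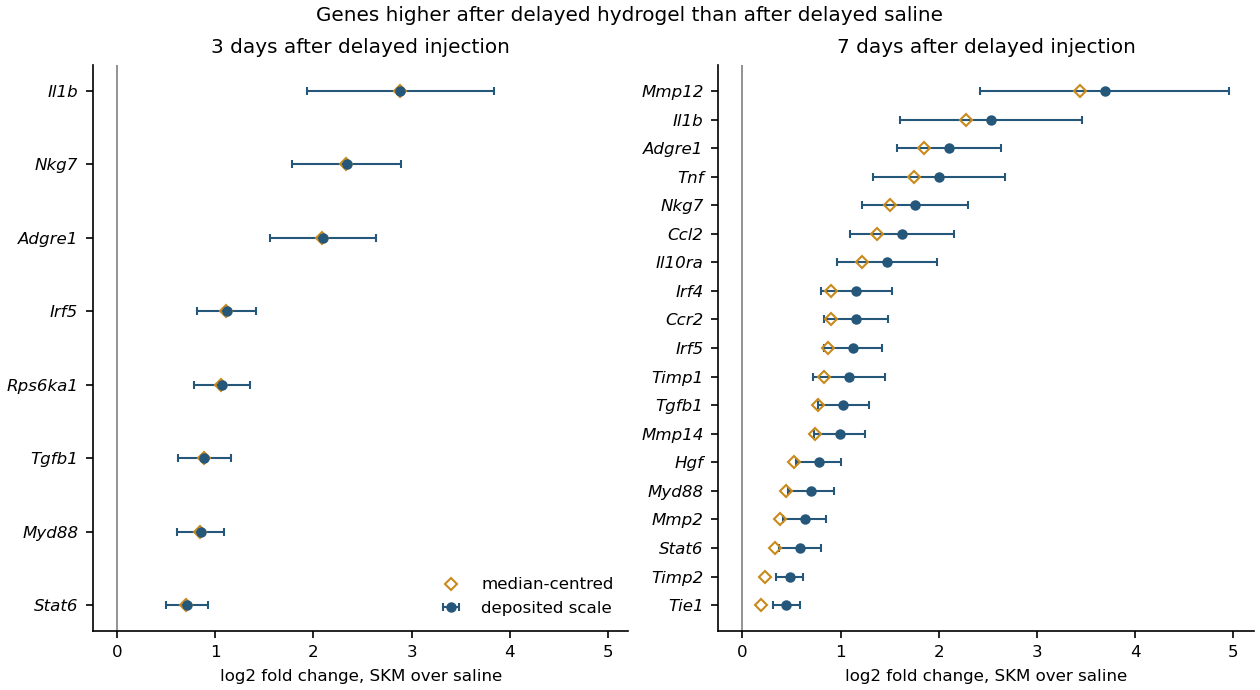
Log2 fold change ± SE (horizontal axis) of SKM against saline for genes called at day 3 and at day 7 after delayed injection (vertical axes), with diamonds for the values after centring on the panel median. All points lie above 0, and the centred values at day 7 lie to the left of the others by 0.25.

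At week 8 after delayed injection limma called 0 genes (n = 6 and 5), with 2 genes at an unadjusted p under 0.05, 0 with voom weights and 1 with array weights. The smallest p-values were those of Ccn4 (-1.39 ± 0.52), the hyaluronan synthase genes Has1 (-1.15 ± 0.57) and Has2 (-0.79 ± 0.45), Myf5 (-0.43 ± 0.27) and Pdgfa (-0.24 ± 0.15), all with an adjusted p of 0.998. Adgre1 was at 0.67 ± 0.70. Fry and camera called 0 lists.

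The difference between SKM effects was tested as an interaction. At day 7 the signed effect of SKM after delayed injection minus that after immediate injection was 1.21 ± 0.33 for Hgf and 0.70 ± 0.20 for Itga1 (limma adjusted p = 0.0409 for both; n = 9, 10, 8 and 9). Hgf was at 0.78 ± 0.23 after delayed and -0.43 ± 0.24 after immediate injection, and Itga1 at 0.25 ± 0.14 and -0.44 ± 0.14. These were the 2 genes called, of 40 at an unadjusted p under 0.05; after centring, with a shift of 0.38, and with voom weights the count was 0. It was 0 without immediate saline replicate 2 or 7, immediate SKM replicate 1, 2, 3, 5 or 6, delayed saline replicate 3, 5 or 9, or delayed SKM replicate 4, 8 or 9. It was 5, 21, 18 and 5 without immediate saline replicates 1, 4, 6 and 8, 28 and 7 without immediate SKM replicates 7 and 8, 4, 4, 14 and 14 without delayed saline replicates 1, 2, 6 and 10, and 27, 6, 4, 7 and 4 without delayed SKM replicates 1, 3, 5, 6 and 7.

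At day 3 the same difference called 0 genes by limma, with 33 at an unadjusted p under 0.05, 6 with voom weights and 75 with array weights, led by Rps6ka1 (1.27 ± 0.40), Myf5 (-0.93 ± 0.30) and Stat6 (0.94 ± 0.31, adjusted p = 0.0864 for all 3), and 12 genes were called without immediate saline replicate 3. Between day 7 and day 3 the effect of immediate SKM differed for 0 genes by limma, with 7 at an unadjusted p under 0.05, 1 with voom weights and 11 with array weights. Myh3 (-3.03 ± 0.88) and Myf5 (-0.997 ± 0.304) had an adjusted p of 0.0939, and Pax7, a marker of muscle stem cells, was at -0.96 ± 0.39; 2 genes were called without immediate saline day 3 replicate 7 or 9, immediate saline day 7 replicate 4, or immediate SKM day 7 replicate 4 or 8. For delayed SKM the same difference called 0 genes, with 1 at an unadjusted p under 0.05 and 0 with voom or array weights, and the smallest p-values were those of Myf5 (0.62 ± 0.30), Tie1 (0.33 ± 0.20) and Pdgfa (0.27 ± 0.17).

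The last question was whether the saline injection itself set injured muscle apart from injury alone. At day 3 after immediate injection the saline samples stood above SBI day 3 for 60 genes and below it for none (n = 9 and 8), among them Nos2 (3.09 ± 1.05), Mmp8 (2.97 ± 0.66), Il23a (2.41 ± 0.66), Ccl3 (2.24 ± 0.67) and Arg1 (1.80 ± 0.62). The panel median lay 0.63 higher, and after centring 1 gene was called, Mmp8 (2.35). At day 7 after immediate injection 4 genes were higher than at SBI day 7 (n = 9 and 6), Gsk3b (0.54 ± 0.13), Foxo3 (0.46 ± 0.14), Itgb1 (0.45 ± 0.11) and Prkaa1 (0.38 ± 0.10), with a shift of 0.29 and 0 genes after centring. That count was 1, 12, 7, 11 and 0 without SBI day 7 replicates 1, 3, 4, 5 and 6. The name Prkaa1 rests on a match that was the best by a narrow margin only.

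The delayed saline groups were set against SBI days 31, 35 and 84, a match that rests on the study's timing as known and not on the labels. At day 3 after delayed injection Adam12 stood 1.93 ± 0.40 above SBI day 31, and Il33 (-0.66 ± 0.18) and App (-0.49 ± 0.14) below it (n = 9 and 6); these were the 3 genes called, and 3 were called after centring. The count was 1 without SBI day 31 replicate 1, 1 without its replicate 6, 1 without saline replicate 1, 5 without saline replicate 2 and 0 in a fit of these groups only. At day 7 after delayed injection Myh3 stood 1.68 ± 0.67 above SBI day 35, and 72 genes stood below it (n = 10 and 6), led by Fst (-1.33 ± 0.30), Hgf (-1.29 ± 0.26), Mmp14 (-1.24 ± 0.29), the fibroblast receptor gene Pdgfra (-1.19 ± 0.17) and Ptn (-1.14 ± 0.27). The panel median lay lower by -0.68, and after centring 2 genes were called, Myh3 higher (2.36) and Pdgfra lower (-0.51). At week 8 limma called 0 genes against SBI day 84 (n = 5 and 6), with 1 at an unadjusted p under 0.05 and 0 with voom or array weights, and Hgf was at 0.58 ± 0.30 and Has1 at 1.06 ± 0.57. For the delayed day 7 comparison the authors' deposited table gives fold changes that lie higher than those of the value table by a median of 0.66 over 10 genes (median deviation 0.0135), and for the delayed day 3 comparison by 0.18 over 20 genes (0.0059), so the value table scales these 2 pairs of groups otherwise than the authors' fold changes do. At delayed day 3 this offset is not the size of the panel shift of -0.09. For immediate day 3 the offset was -0.18 over 17 genes and not constant (median deviation 0.139), for immediate day 7 it was -0.06 over 2 genes, and for week 8 the authors' table gives no values.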

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

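The rules that picked the results of this part were fixed in advance; the 6 genes to which the rule for single samples was applied were chosen after their values were seen. A sample was picked when its gap to the nearest other sample of its group was large for the group's range by Dixon's test, in groups of 4 to 10 samples. It was applied to the total count, the panel median, the injury score and the 6 genes of the time course figure (Ccl2, Timp1, Myh3, Myh1, Col3a1 and Mstn). It picked 8 of 129 sets of values, and chance picks about 1 in 20.

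SBI day 3 replicate 8 had a total count of 366294, against 1127073 to 1713607 in the other 7 samples of its group. SBI day 31 replicate 1 had the highest Ccl2, 10.38 (log2), against 6.29 to 7.64 in the other 5 samples, and the lowest Myh1, 16.74 against 17.32 to 17.66. Immediate saline day 7 replicate 7 had the highest Timp1, 14.23 against 11.04 to 12.59 in the other 8 samples, and the lowest Myh1, 14.43 against 16.51 to 17.50. In both samples an inflammatory or matrix gene was high where a fast myosin gene was low, the directions these genes took at SBI days 1 and 3. The number of picks is near that of chance, and a likeness of these samples to early injury was not tested. Myh1 was also lowest in delayed SKM day 3 replicate 1 (15.53, against 16.37 to 17.16 in the other 8) and in delayed SKM week 8 replicate 5 (14.92, against 15.72 to 15.94 in the other 5). Mstn was lowest in SBI day 84 replicate 4, 6.26 against 7.76 to 8.29 in the other 5 samples.

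An interaction test in limma called the difference between the delayed and the immediate effect of SKM at day 7 for Hgf (1.21 ± 0.33) and Itga1 (0.70 ± 0.20), with an adjusted p of 0.0409 for both. Other splits of the samples do not exclude chance (7 of 100 as large, the highest with 46 genes against the 2 here), and leaving out 1 sample took the count to between 0 and 28. Hgf was above the saline mean in 9 of 9 delayed SKM samples. After centring on the panel median the differences were 0.82 for Hgf and 0.31 for Itga1, and neither passed.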

How the results depend on the processing

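The alternatives chosen after the data were seen are voom weights on the recovered counts, samples of at least 1000000 counts only, repeated samples kept separate, SBI days 3 and 7 from replicates 1 to 6, and the F test without SBI day 84. A count of genes or lists is given below where it moved by over 1.5 times. Each comparison below is injury against uninjured muscle or SKM against saline unless another is named.

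Array weights changed the counts of genes to 33 at SBI day 10 and 7 at SBI day 31. For immediate SKM they gave 31 at day 3 and 4 at day 7. For delayed SKM they gave 61 at day 3 (36 higher and 25 lower), 56 at day 7 (46 higher and 10 lower) and 1 at week 8. For saline against injury alone they gave 2 at immediate day 7 and 32 at delayed day 3, for SBI day 31 against day 7 they gave 93, and for the difference of SKM effects 11 between immediate days 7 and 3, 75 between delayed and immediate at day 3 and 39 between them at day 7.

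Centring on the panel median gave 5 genes at SBI day 10, 2 at SBI day 84, 15 for delayed SKM at day 3 and 10 at day 7. It gave 1 gene for immediate saline day 3 against SBI day 3, 0 for immediate saline day 7 against SBI day 7, 2 for delayed saline day 7 against SBI day 35, and 0 for the difference between delayed and immediate SKM at day 7. Lists called by fry after centring were 0 at SBI day 10, 0 at SBI day 84, 1 for immediate SKM at day 3, 2 for delayed SKM at day 3 and 1 at day 7. With camera the lists called were 0 at SBI days 1, 3, 7, 10 and 84, 1 for immediate SKM at day 3 and 0 for delayed SKM at day 7.

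A fit of the compared groups only gave 2 genes at SBI day 7, 4 at SBI day 10, 48 for delayed SKM at day 3 and 12 at day 7. It gave 0 genes for immediate saline day 7 against SBI day 7, 0 for delayed saline day 3 against SBI day 31, 1 for delayed saline at week 8 against SBI day 84, 4 for SBI day 7 against day 3 and 7 for SBI day 31 against day 7. For delayed minus immediate SKM it gave 12 at day 3 and 1 at day 7. It called 5 lists at SBI day 1, 0 at SBI day 7 and 1 at SBI day 10. For delayed SKM it called 4 lists at day 3 (2 higher and 2 lower) and 2 at day 7, both higher.

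Samples of at least 1000000 counts gave 5 genes for delayed SKM at day 3, 44 at day 7, 0 for immediate saline day 7 against SBI day 7, 1 for delayed saline day 3 against SBI day 31, 75 for SBI day 7 against day 3, 29 for SBI day 31 against day 7 and 25 for delayed minus immediate SKM at day 7. Voom weights gave 2 genes at SBI day 31, 13 for delayed SKM at day 7, 1 for immediate SKM day 7 minus day 3, 6 for delayed minus immediate SKM at day 3 and 0 at day 7. Without the lowest 25% of genes the counts were 13 for delayed SKM at day 7 and 7 for delayed minus immediate SKM at day 7. A pseudocount of 10 gave 4 for the last of these. Keeping the repeated samples separate gave 16 genes for immediate saline day 7 against SBI day 7. The replicate number as a block (replicate block) gave 35 genes for delayed SKM at day 7 and 4 for delayed minus immediate SKM at day 7, although samples of the same number do not pair by their values.

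Leaving out 1 sample at a time gave 44 to 81 genes at SBI day 7, 2 to 17 at SBI day 10, 0 to 6 at SBI day 31, 4 to 15 for delayed SKM at day 3 and 0 to 43 at day 7. It gave 0 to 12 for immediate saline day 7 against SBI day 7, 1 to 5 for delayed saline day 3 against SBI day 31, 31 to 67 for SBI day 7 against day 3, 24 to 76 for SBI day 31 against day 7, 0 to 2 for immediate SKM day 7 minus day 3, 0 to 12 for delayed minus immediate SKM at day 3 and 0 to 28 at day 7. The other ranges included 71 to 97 at SBI day 1, 88 to 100 at SBI day 3 and 98 to 108 at SBI day 84.

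Some directions turned around. Centring moved every gene at SBI day 84 by the same 1 shift. Igf1r stood higher after it (0.68) and passed. A further 9 genes picked by the naming rule, lower on the deposited scale, stood above uninjured muscle after it, Myd88 (0.29), Ccr2 (0.0785), Il33 (0.36), Stat6 (0.22), Dmd (0.28), Smad4 (0.0166), Foxo3 (0.22), Timp2 (0.19) and Utrn (0.0512), and so did 4 lists, acute inflammation, type 2 and regulatory immune, adult muscle fibre and neuromuscular junction (adjusted p = 0.771 for each, and 0.227 to 0.839 over all lists). With camera, whose direction is relative to the rest of the panel, the direction turned for the fibroblast and TGF-beta list at SBI day 1 (adjusted p = 0.987), and at SBI day 84 for acute inflammation (0.584), the type 2 and regulatory immune list (0.789), adult muscle fibre (0.674), ECM remodelling enzymes (0.789) and neuromuscular junction (0.903). Apart from that of Igf1r, none of the values in this paragraph passed.

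Of the values of genes picked by the naming rule, which the text gives in part, centring left 335 the same, 56 weaker, 4 stronger and 9 of opposite sign; voom weights left 371 the same, 26 weaker and 7 stronger; and leaving out 1 sample at a time left 4738 the same, 277 weaker and 63 stronger. The injury scores passed no test under any alternative that was run, and with 1 sample left out they ran from -0.315 to -0.095 at immediate day 3, from -0.306 to -0.0023 at immediate day 7 and from 0.0384 to 0.133 at week 8. Centring on housekeeping genes was not run, since the panel values hold none. The depth minimum was not run for SBI days 10, 31 and 84, week 8 and the F test, and centring not for the score of week 8.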

Other observations

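The splits of the samples and the tests of a single scaling factor at day 84 and of a returning injury profile were planned before their results were seen, and the other tests and the choice of genes in this part were made after. Of the 35 panel genes on no list, 7 rose and 17 fell at SBI day 1, 12 rose and 16 fell at day 3, and 11 rose and 13 fell at day 7 (limma, n = 3, 8 and 6 against 3). No test groups these genes. Among those that fell at all 3 days, at day 3 Mylk2 was at -3.70 ± 0.72, Mybpc1 at -3.14 ± 0.51, Tcap at -3.04 ± 0.65, Mybpc2 at -2.90 ± 0.60, Tmod1 at -2.53 ± 0.43 and Jsrp1 at -2.44 ± 0.42. The translation factor genes Eif4b (-1.10 ± 0.18), Eif4g1 (-1.08 ± 0.19) and Eif2b5 (-1.13 ± 0.18) also fell at day 3. The tropomyosin gene Tpm4 rose at all 3 days (1.42 ± 0.39, 2.06 ± 0.33 and 1.01 ± 0.34). The transcription factor genes Irf5 (2.52 ± 0.44) and Junb (2.38 ± 0.44) rose. Ptn, which encodes a secreted growth factor, fell at day 1 (-1.55 ± 0.42) and rose at day 3 (2.13 ± 0.35) and day 7 (1.62 ± 0.36). At SBI day 7 the injury score ran from 0.41 in replicate 5 to 2.38 in replicate 1, so the samples of that day lay at unlike distances from uninjured muscle.

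Other splits of the samples into groups of the same sizes were counted, the real one included. At SBI day 1 the real split called 87 genes and the highest other 34, and at SBI day 10 they called 12 and 1; with 10 splits each (1 as large at each day) the share cannot come under 0.05. The share of splits as large was under 0.05 at SBI day 3 (99 genes, highest other 95, 1 of 100 splits as large), SBI day 7 (77 and 91, 4 of 84), SBI day 84 (108 and 81, 1 of 84), and for delayed SKM at day 3 (9 and 10, 2 of 100) and day 7 (20 and 36, 3 of 100). It was also under 0.05 for immediate saline day 3 against SBI day 3 (60 and 39, 1 of 100), delayed saline day 3 against SBI day 31 (3 and 2, 1 of 100), delayed saline day 7 against SBI day 35 (73 and 51, 1 of 100) and the F test (132 and 129, 1 of 100). These shares are not adjusted over the comparisons. At SBI day 7 and for delayed SKM at days 3 and 7 another split called more genes than the real one. Such shares make chance less likely and do not exclude it. The share was 0.05 or more for immediate saline day 7 against SBI day 7 (4 and 71, 21 of 100), SBI day 7 against day 3 (47 and 68, 5 of 100), SBI day 31 against day 7 (56 and 62, 5 of 100) and delayed minus immediate SKM at day 7 (2 and 46, 7 of 100).

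Where limma called 0 genes, every split counts as large by construction, so the count tests nothing there; the median of the other splits was 0, and 2 to 12 of them called any gene. The highest other split called 9 genes at SBI day 31 and 2 at SBI day 35 (84 of 84 splits), and among 100 of 100 splits 19 for immediate SKM at day 3, 54 for immediate SKM at day 7, 1 for delayed SKM at week 8, 1 for delayed saline at week 8 against SBI day 84, 67 for immediate SKM day 7 minus day 3, 45 for delayed SKM day 7 minus day 3 and 34 for delayed minus immediate SKM at day 3. Of the comparisons with called genes, other splits called several times the real count for immediate saline day 7 against SBI day 7 and for delayed minus immediate SKM at day 7, which points to a structure of the samples that no test here addressed.

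The first pattern weighed was that all 108 called genes were lower at SBI day 84. If a single scaling factor lowered these samples, the called genes would spread around their median about as widely as at SBI day 35, and the SD was 1.353 times as wide, within the limit of 1.5 set beforehand. The called genes were chosen on these same fold changes, all of them lower, which narrows their spread at day 84. The ratio therefore cannot decide for a single factor. A loss of low-count probes is excluded as the whole cause, since the 34 genes of the highest 25% by uninjured level, called or not, had a median of -1.72. A biological fall of the whole panel at day 84 stays open and untested, because the day cannot be parted from the scale of its samples.

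The second pattern was the shift of the whole panel between saline-injected and uninjected injured muscle. For delayed saline day 7 against SBI day 35 the authors' fold changes lay above those of the value table by 0.66, close to the shift of -0.68 with its sign turned, so separate scaling may be the whole shift there. For immediate saline day 3 against SBI day 3 the shift was 0.63, and the authors' values differed from the table by -0.18 over 17 genes, or by -0.35 (median deviation 0.0406) with the subset of injury samples that brings them closest. Over all samples the offset was not constant over the genes (median deviation 0.139). With the closest subset it was constant within the limit of 0.05 and smaller than the shift, but that subset was chosen on these same values. No source says that the authors' values share 1 scale, so separate scaling stays open there. The value table itself scales 1 set of SBI day 3 counts in 2 ways. Replicates 6 and 7 had the same counts, and their factors differed 1.43-fold (0.51 log2). How the other samples of that day were scaled cannot be read from this pair. A response of the muscle to the injection itself stays open too and was not tested.

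The third pattern was the higher level of immune genes after delayed SKM, for which a scaling difference is excluded as the whole cause. The acute inflammation, type 2 and regulatory immune and macrophage lists (24 genes) were set against the other 110 genes, which cancels a shared factor. These others included Il2 and Tbx21 of the lymphocyte list. The difference was higher with SKM by 0.997 at day 3 (exact permutation adjusted p = 0.00214, above the saline mean in 8 of 9 samples) and 0.801 at day 7 (adjusted p = 0.0166, 8 of 9). At day 7 the panel shift was 0.25, and centring took the calls from 20 higher to 6 higher and 4 lower. Fry then called neither immune list, so scaling as a part of the cause stays open at that day. A lower share of muscle fibre RNA would raise all other cell types alike. The same 24 genes minus 6 endothelial and fibroblast markers (Kdr, Flt1, Tie1, Pdgfra, Col1a1 and Col3a1) were higher by 0.858 at day 3 (exact permutation adjusted p = 0.00439, 8 of 9) and 0.546 at day 7 (adjusted p = 0.0319, 7 of 9). These values argue against a lower fibre share as the whole cause, but they do not exclude it. At day 3 some alternatives also called lower genes, where the main fit called none. A fit of the compared groups only called 23 genes higher and 25 lower, with 2 lists higher and 2 lower. Array weights called 36 higher and 25 lower. A lower fibre share as a part of the cause therefore stays open. The markers were put in place of 3 gene lists after the results for those lists had been seen. Flt1 was called lower at SBI days 3 and 7, and after centring Kdr at day 3. Tie1 was itself called higher with delayed SKM at day 7. A candidate explanation is that delayed SKM brings back part of the profile of early injury. It was examined over the genes lower at the same day after injury on the centred scale, a set other than that of the injury score. Their signed distance from uninjured muscle was higher with SKM by 0.356 at day 3 (50 genes, exact permutation adjusted p = 0.013, 7 of 9) and 0.463 at day 7 (35 genes, adjusted p = 0.0154, 8 of 9). On the deposited scale it was 0.351 (exact permutation p = 4.11e-05) and 0.209 (p = 0.0796, 6 of 9). At day 7 the 2 scales part by the panel shift of 0.25, so that day stays undecided. These sets include fibre genes, so a lower share of fibre RNA would raise the distance too, and the test cannot part the 2 explanations. Over all genes called after injury the difference was 0.559 (102 genes) and 0.504 (78 genes), which decides nothing, because these include the immune genes that prompted the explanation. These data cannot show whether immune cells entered the muscle or resident cells changed, and the hypothesis was formed after the genes of delayed SKM had been seen.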
